A study of Mus musculus with 40 samples.

How the data were processed

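The 40 arrays hold RNA of the mouse plasmacytoma line J558LuM transduced with an empty vector (MIR), PAX5-WT, PAX5-G183S, PAX5-G183V (7 arrays each), PAX5-P80R or PAX5-Δ2-6 (6 arrays each). The deposited values are log2 signals, 1 per probe set and array, made by the authors with RMA per the submitters' processing notes; the version and the software are not given in the sources used here. They were used as deposited, since raw signals were not used here. Array medians lay between 4.21 and 4.27, and the closest pair of arrays had r = 0.9969 with 0 identical columns. The number of arrays limits the precision, with a median SE of 0.08 on the log2 scale for a comparison of PAX5-WT with MIR.

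Of 45141 probe sets 28898 name 1 gene, 551 several and 15692 none. The probe set with the highest mean over all arrays stood for each of 17097 genes. Probe sets that name no single gene were tested apart.

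Groups, plates, isolation batches and transduction numbers were taken from the labels. R 4.3.3 with limma 3.58.1 and statmod 1.5.0 fitted each gene with a term for each of 6 groups, the plate (2) and the RNA isolation batch (2), and the standard errors are those of limma after moderation. For each of 10 comparisons p-values were adjusted by Benjamini and Hochberg over all genes, and a gene was called at an adjusted p under 0.05. An isolation batch by group term was tested for the 5 comparisons with MIR. The 19 gene lists (378 genes, 328 of them measured, 8 by a synonym) were written from textbook knowledge before the data were examined and tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. Lists were also adjusted over their own genes alone. Other cell types were covered by lists of fibroblast, T cell, myeloid and erythroid markers.

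The share of the wild-type response was the mean signed level after removal of the plate effect, scaled within each isolation batch to MIR at 0 and PAX5-WT at 100, over genes called between PAX5-WT and MIR in the isolation batch that was not scored, in a fit of the PAX5-WT and MIR arrays alone. Groups were compared by an exact permutation within isolation batches, adjusted over the 8 tests. Correlations and overlaps that share the MIR or PAX5-WT arrays were set against 100 simulated draws of unchanged groups and against the same values with the shared arrays split in 2 parts.

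Genes were named by a rule fixed in advance: up to 10 with the largest rise and 10 with the largest fall among called genes of a comparison, up to 4 per list with the largest change in size, and Pax5 and Cd79a. Some items are not reported here. Genes chosen otherwise are said to have been chosen after their values were seen.

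The procedure was tested on simulated data with 200 changed genes, changed 1.2-fold to 4-fold. The noise was drawn independently for each gene, without a difference between transduction series. Of 50 genes changed 1.5-fold, 94% were recovered for PAX5-WT against MIR, 94% for PAX5-P80R against MIR and 94% for PAX5-Δ2-6 against MIR, and of 50 genes changed 1.2-fold 52%, 38% and 40%. A simulated share of 50% was scored as 49.4%.

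Alternatives were no batch terms, single plates and isolation batches, batch as a random block, 3 transduction number series, a replicate block, only the 2 groups compared, the mean of all probe sets of a gene, quantile normalization applied again, arrays centred on their medians, a filter on dim genes, trend and robust settings, array weights, a 1.5-fold minimum and each array left out in turn. Those chosen after seeing the data were leaving out 3 arrays, 4 transduction series and PAX5-Δ2-6 as the control.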

Results

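The 40 arrays measured total RNA from J558LuM cells, a mouse plasmacytoma line that lacks PAX5. The cells were transduced with an empty vector (MIR), with wild-type PAX5 (PAX5-WT) or with 1 of 4 altered constructs. PAX5 is the transcription factor that sets and keeps B cell identity. PAX5-P80R carries a change in the paired DNA-binding domain, PAX5-G183S and PAX5-G183V carry changes in the octapeptide motif that binds co-repressors, and the labels give the last construct only as PAX5-Δ2-6. The title of the series concerns inherited PAX5 changes and susceptibility to pre-B cell acute lymphoblastic leukaemia, and the comparisons ask how far each construct does what wild-type PAX5 does. MIR, PAX5-WT, PAX5-G183S and PAX5-G183V had 7 arrays each, 4 on plate 1 and 3 on plate 2. PAX5-P80R and PAX5-Δ2-6 had 6 arrays each, all on plate 2. Each array came from its own transduction, so p-values measure the spread between transductions of 1 cell line within groups, plates and isolation batches. The fit had no term for the transduction series described below. In comparisons across series the p-values therefore leave out any difference between series. Medians of the arrays lay between 4.21 and 4.27 on the log2 scale, and the number of arrays limits the precision.

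The labels number the transductions and name 2 RNA isolation batches. Transductions 34 to 44 and 58 to 66 held the MIR, PAX5-WT and PAX5-G183S arrays, and transductions 1 to 9 and 45 to 57 held the PAX5-G183V, PAX5-P80R and PAX5-Δ2-6 arrays. PAX5-G183S replicate 4 was the exception, with transduction 45. Isolation batch 1 covered the numbers 1 to 44 and isolation batch 2 the numbers 45 to 66. Comparisons of PAX5-G183V, PAX5-P80R or PAX5-Δ2-6 with MIR, PAX5-WT or PAX5-G183S therefore ran across transduction series, and the counts of genes within each isolation batch are given beside the pooled ones. An alternative fit took 3 series, with the numbers 1 to 9, 34 to 44 and 45 to 66. Only the last held all groups. That fit therefore estimates comparisons across series from isolation batch 2, where the numbers 45 to 57 and 58 to 66 still part them.

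PAX5-WT was compared with MIR to find what wild-type PAX5 moved in these cells. Cd36, a scavenger receptor that carries fatty acids, rose by 6.32 ± 0.27 on the log2 scale (SE, n = 7 and 7; limma adjusted p = 1.9e-19). Ms4a1, which encodes a surface antigen of B cells, rose by 5.29 ± 0.28, Nav3, a microtubule-binding protein, by 5.11 ± 0.37 and Fcgr2b, the inhibitory Fc receptor of B cells, by 4.85 ± 0.27. Ets1 and Ablim1 rose by 2.68 ± 0.20 and 2.58 ± 0.20, and Siglecg, an inhibitory receptor of B cells, by 2.43 ± 0.18. Asb9 fell by 3.53 ± 0.15 (adjusted p = 1.7e-19) and Mycn, a transcription factor of the MYC family, fell by 2.01 ± 0.14. In Cd36, Ms4a1, Nav3, Fcgr2b, Asb9 and Mycn all 7 PAX5-WT arrays lay beyond every MIR array. Cd36 lay between 3.56 and 3.85 in 6 MIR arrays and at 5.89 in MIR replicate 7, without which it rose by 6.61 ± 0.24. At such low levels the size of a rise depends on the background signal. Over 17097 genes, 613 rose and 486 fell, 1099 in all, of which 145 changed at least 1.5-fold. Isolation batch 1 alone gave 810 genes and isolation batch 2 alone 229, with 188 called in both in the same direction. Slamf6, a lymphocyte surface receptor, rose by 1.52 ± 0.22 in isolation batch 1 and by 4.21 ± 0.25 in isolation batch 2, a difference with adjusted p = 8.2e-05, and by 2.67 ± 0.36 over both.

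Some members of the B cell lists rose with PAX5-WT, and most did not pass. Of 23 measured B lineage transcription factors 4 rose and 19 did not pass: Ets1, Spib by 1.68 ± 0.29, Id3 by 0.59 ± 0.18 and Ikzf1, chosen after its value was seen, by 0.35 ± 0.04. With p-values adjusted over the list alone, 5 rose, and camera placed the list above other genes (adjusted p = 0.000564, and adjusted p = 0.0642 with an estimated correlation). Of 24 genes of B cell receptor signalling 5 rose, among them Fcgr2b and the kinase Btk by 0.42 ± 0.06, 1 fell and 18 did not pass. Adjusted over the list alone, 8 rose and 1 fell (camera adjusted p = 0.000564, and adjusted p = 0.0642 with an estimated correlation). Of 14 genes of MHC class II presentation 5 rose, H2-DMa by 1.36 ± 0.16 and the invariant chain gene Cd74 by 0.59 ± 0.12 among them, and 9 did not pass. With p-values adjusted over the list alone, 7 rose and 1 fell (camera adjusted p = 0.00335, and adjusted p = 0.113 with an estimated correlation). Of 26 genes that PAX5 activates in B cells 4 rose (Slamf6, Siglecg, Spib and Id3), Mycn fell and 21 did not pass. Adjusted over the list alone, the counts were 4 and 1 (camera adjusted p = 0.0384, and adjusted p = 0.113 with an estimated correlation).

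Some plasma cell identity genes fell with PAX5-WT, as did some genes of the unfolded protein response, cholesterol synthesis and the cell cycle. Of 16 plasma cell identity genes 4 fell and 12 did not pass. Ly6c1, a surface marker of plasmacytoma cells, fell by 0.92 ± 0.08, the elongation factor gene Ell2 fell by 0.33 ± 0.06, its partner Eaf2 fell by 0.22 ± 0.05 and Xbp1, a regulator of secretion, fell by 0.14 ± 0.04; Eaf2 and Xbp1 were chosen after their values were seen. With p-values adjusted over the list alone, 1 rose and 7 fell (camera adjusted p = 6.85e-05, and adjusted p = 0.0642 with an estimated correlation). Of 20 genes of the unfolded protein response 3 fell, Pdia4 and Edem1 among them, and 17 did not pass. Adjusted over the list alone, 2 rose and 3 fell (camera adjusted p = 0.592, and adjusted p = 0.991 with an estimated correlation). Of 18 genes of cholesterol synthesis 3 fell, with Cyp51 at -0.27 ± 0.04 and Sc5d at -0.26 ± 0.05, and 15 did not pass. With p-values adjusted over the list alone, 7 fell (camera adjusted p = 0.000454, and adjusted p = 0.0642 with an estimated correlation). Of 27 cell cycle genes 5 fell, both over all genes and adjusted over the list alone, and 22 did not pass, with the proliferation marker Mki67 at -0.29 ± 0.06 and the mitotic kinase Aurka at -0.20 ± 0.05 (camera adjusted p = 0.00783, and adjusted p = 0.107 with an estimated correlation).

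Other lists went both ways with PAX5-WT. Of 26 genes that PAX5 represses in B cells, 1 rose, 2 fell and 23 did not pass. The receptor kinase gene Flt3, a textbook target of repression, was the one that rose, by 1.33 ± 0.13, while the adaptor gene Grap2 fell by 0.53 ± 0.09 and Xbp1 fell as given above. Adjusted over the list alone, 1 rose and 3 fell (camera adjusted p = 0.548, and adjusted p = 0.516 with an estimated correlation). Of 25 interferon response genes 3 rose and 3 fell, with Irgm1 at 1.05 ± 0.07, Zbp1 at -0.63 ± 0.07 and Igtp at -0.44 ± 0.07, and 19 did not pass. With p-values adjusted over the list alone, 4 rose and 3 fell (camera adjusted p = 0.994). Of 16 genes of adhesion and migration the integrin gene Itga4 fell by 1.02 ± 0.12, Cd44 fell by 0.40 ± 0.07 and the sphingosine receptor gene S1pr2 rose by 0.62 ± 0.12. In all 1 rose, 3 fell and 12 did not pass, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.748). Of 19 genes of p53 and apoptosis 3 rose, 2 fell and 14 did not pass. The survival gene Bcl2 was 0.58 ± 0.08 higher and the pro-apoptotic Pmaip1 was at -0.54 ± 0.11. Adjusted over the list alone, the counts were again 3 and 2 (camera adjusted p = 0.988).

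Lists of other cell types stayed near the vector control in PAX5-WT arrays. With limma 0 of 14 fibroblast, 0 of 13 T cell, 0 of 15 myeloid and 0 of 11 erythroid markers passed, with unadjusted p under 0.05 for 2, 1, 1 and 2 of them. With p-values adjusted over the list alone, 1 fibroblast marker rose and 1 erythroid marker fell. Their camera adjusted p-values were 0.994, 0.994, 0.988 and 0.994. Of 8 immunoglobulin genes 0 passed, 2 had an unadjusted p under 0.05, and adjusted over the list alone 0 passed (camera adjusted p = 0.597). Of 18 genes of MYC and ribosome biogenesis 2 rose, also when adjusted over the list alone (camera adjusted p = 0.597). Of 18 genes of glycolysis and hypoxia 1 fell, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.994). The median, the mean and the camera direction differed in sign for the PAX5-repressed, unfolded protein response, interferon, adhesion, T cell and erythroid lists. The probe set of Pax5 lay near the array median, with a mean of 4.47 in MIR, and its change of 0.30 ± 0.15 in PAX5-WT did not pass (adjusted p = 0.30). Whether it covers the transduced construct is not given in the sources used here. Cd79a, a PAX5 target in B cells, lay near the array median as well, and its difference was 0.01 ± 0.08 (adjusted p = 0.97).

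**Figure D1:**
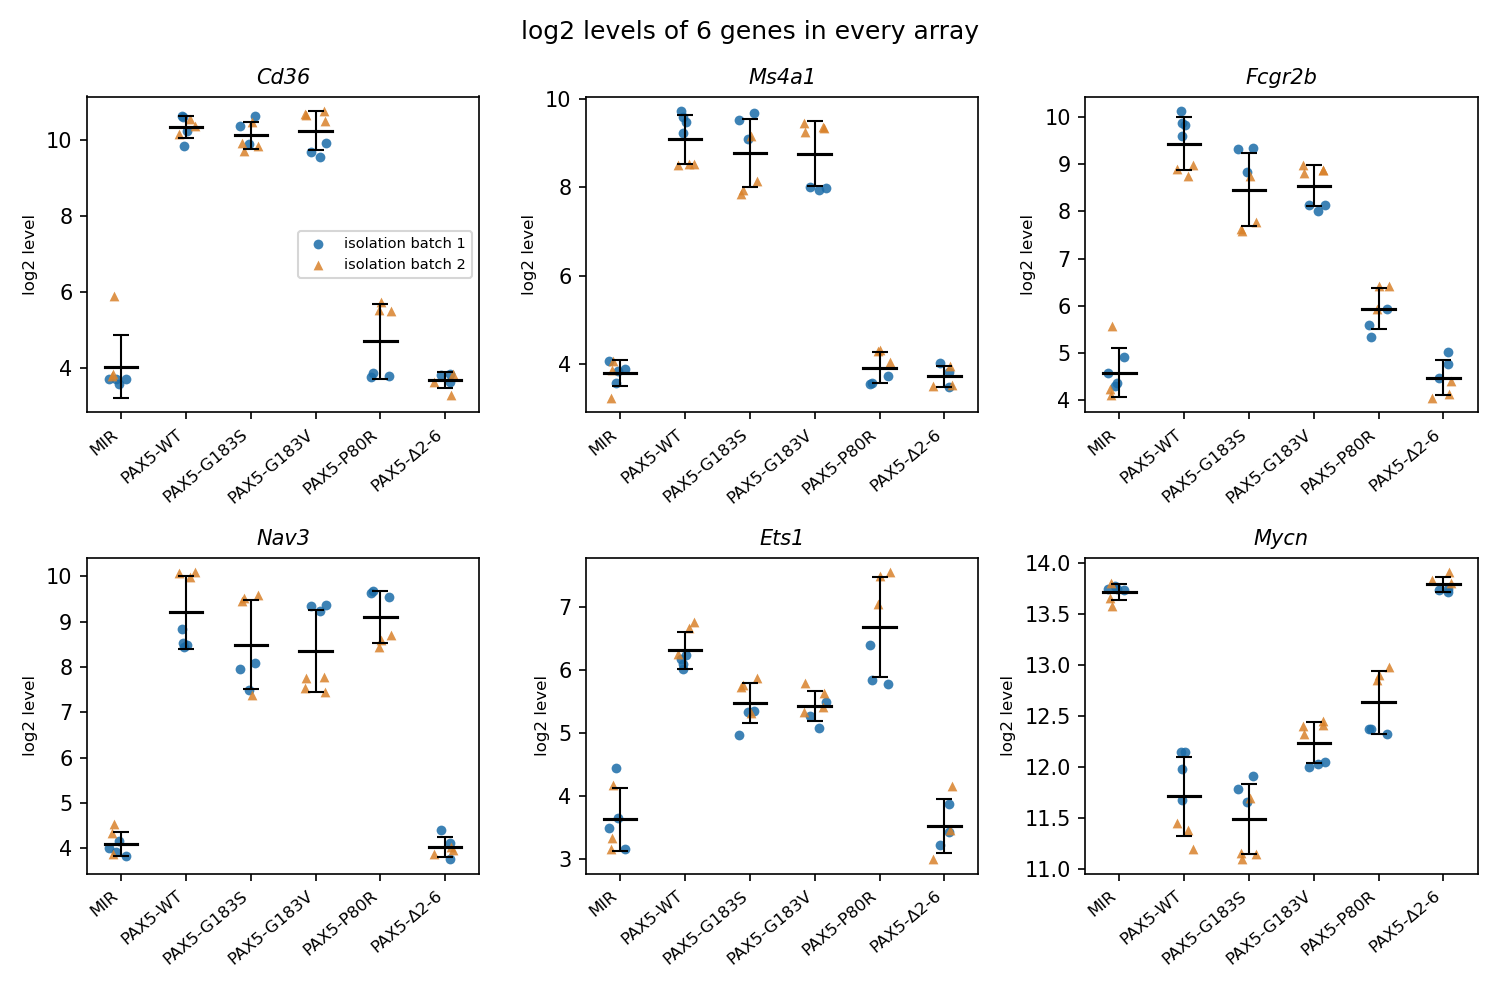
Levels of 6 genes on the log2 scale (y axis) in every array of the 6 groups (x axis), with isolation batch 1 as circles, isolation batch 2 as triangles, and the mean with its SD in black. Cd36, Ms4a1 and Fcgr2b were high in PAX5-WT, PAX5-G183S and PAX5-G183V, while Nav3 and Ets1 were also high in PAX5-P80R.

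PAX5-G183S was compared with MIR to see what this octapeptide change leaves of the wild-type response. Cd36 rose by 6.03 ± 0.28 (SE, n = 7 and 7; limma adjusted p = 1.1e-18), Ms4a1 by 4.99 ± 0.28, Nav3 by 4.40 ± 0.37 and Fcgr2b by 3.91 ± 0.27. Asb9 fell by 3.42 ± 0.15 and Mycn fell by 2.22 ± 0.14. In all 631 genes rose and 415 fell, 1046 together. Of the genes that PAX5-WT raised 439 also rose here, and of those it lowered 290 also fell, where unrelated lists of these sizes would share 22.6 and 11.8. Both comparisons use the MIR arrays: with these split between them 332 and 352 genes were shared, and simulated unchanged groups shared at most 7. No gene called in both went in opposite directions. Of 23 B lineage transcription factors 6 rose (7 adjusted over the list alone; camera adjusted p = 0.00213, and adjusted p = 0.0954 with an estimated correlation). Of 16 plasma cell identity genes 1 rose and 5 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.00272, and adjusted p = 0.231 with an estimated correlation). Of 24 genes of B cell receptor signalling 5 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00429, and adjusted p = 0.143 with an estimated correlation). Of 27 cell cycle genes 7 fell, the same number as adjusted over the list alone (camera adjusted p = 0.00757, and adjusted p = 0.143 with an estimated correlation). Of 14 MHC class II genes 3 rose (4 adjusted over the list alone) and of 18 cholesterol synthesis genes 3 fell (5 adjusted over the list alone), both with camera adjusted p = 0.0232, and adjusted p = 0.299 with an estimated correlation. Isolation batch 1 alone gave 646 genes and isolation batch 2 alone 319, of which 211 were shared in direction.

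PAX5-G183V was compared with MIR in the same way. Cd36 rose by 6.15 ± 0.28 (SE, n = 7 and 7; limma adjusted p = 5.3e-19), Ms4a1 by 4.98 ± 0.28, Nav3 by 4.25 ± 0.37 and Fcgr2b by 4.00 ± 0.27, while Asb9 fell by 3.36 ± 0.15 and Mycn fell by 1.48 ± 0.14. In all 963 genes rose and 623 fell, 1586 together. Of the genes that PAX5-WT raised 433 also rose, and of those it lowered 292 also fell, where 34.5 and 17.7 would be shared by unrelated lists. With the MIR arrays split, 351 and 341 genes were shared. Of 16 plasma cell identity genes 1 rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.00193, and adjusted p = 0.172 with an estimated correlation). Of 23 B lineage transcription factors 7 rose (8 adjusted over the list alone; camera adjusted p = 0.00382, and adjusted p = 0.172 with an estimated correlation). Of 18 genes of cholesterol synthesis 5 fell (8 adjusted over the list alone; camera adjusted p = 0.00428, and adjusted p = 0.172 with an estimated correlation). Of 24 genes of B cell receptor signalling 4 rose (5 adjusted over the list alone; camera adjusted p = 0.00788, and adjusted p = 0.172 with an estimated correlation). Of 18 genes of MYC and ribosome biogenesis 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0496, and adjusted p = 0.542 with an estimated correlation). Isolation batch 1 alone gave 302 genes and isolation batch 2 alone 1396, with 181 shared in direction, and 177 genes changed by different amounts in the 2 batches, Ms4a1 (4.10 ± 0.20 and 5.65 ± 0.20) and Nav3 (5.36 ± 0.29 and 3.36 ± 0.29) among them. With 3 transduction number series in place of the isolation batches 2420 genes were called, with 4 series 123, and against PAX5-Δ2-6 arrays of the same series 852 genes were called.

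Among markers of other cell types, the T cell marker Cd6 rose by 0.37 ± 0.09 in PAX5-G183S, by 0.57 ± 0.09 in PAX5-G183V and by 0.46 ± 0.10 in PAX5-P80R. In PAX5-G183V the T cell marker Cd8a fell by 0.26 ± 0.08 and Spi1, a myeloid marker that B cells also express, rose by 0.31 ± 0.10, and in PAX5-P80R the myeloid marker Elane rose by 0.22 ± 0.07. These were the only calls among those 4 lists in the comparisons with MIR. With plate 2 arrays alone the Cd6 change in PAX5-G183S was -0.000685 (adjusted p = 0.998).

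PAX5-G183S and PAX5-G183V were compared with PAX5-WT to find where an octapeptide change alters the response. In PAX5-G183S 13 genes differed, 1 higher and 12 lower (limma; unadjusted p under 0.05 for 942). Klhl14, an adaptor of ubiquitin ligases, was lower at -0.81 ± 0.08 (SE, n = 7 and 7; adjusted p = 7.0e-08), Themis2, a signalling adaptor of B cells, at -0.73 ± 0.08 and the ciliary gene Lca5 at -0.59 ± 0.06, and Usp2, a deubiquitinase gene, was higher by 0.51 ± 0.09. Rbms1, Zc3h12c, Fam111a, Inpp4b, Tspan15 and Traf5 were lower too, at -0.72 ± 0.15, -0.64 ± 0.10, -0.51 ± 0.10, -0.50 ± 0.10, -0.44 ± 0.07 and -0.42 ± 0.07. Rbms1 did not pass in PAX5-G183V over both isolation batches, but it was lower there in each batch alone, at -0.65 and -0.57 (limma adjusted p = 0.00205 and 0.0127). All 7 PAX5-G183S arrays lay below every PAX5-WT array in Klhl14 and Themis2. In PAX5-G183V 25 genes differed, 9 higher and 16 lower, with Ets1 at -0.93 ± 0.20 and Epsti1 at -0.74 ± 0.14 lowest and Fhod3 at 0.75 ± 0.17 highest. These 3 passed in isolation batch 2 alone (-1.07, -0.92 and 1.22) and not in isolation batch 1 alone (-0.82, -0.61 and 0.24). Klhl14 (-0.46 ± 0.08), Themis2 (-0.47 ± 0.08), Lca5 (-0.42 ± 0.06), Fam111a (-0.54 ± 0.10) and 4833439L19Rik (-0.21 ± 0.04, named after its value was seen) were lower in both, 5 genes where 0.0112 would be shared by unrelated lists. Both comparisons use the PAX5-WT arrays, and 100 simulated pairs of unchanged groups against shared controls gave at most 0 such genes. With the PAX5-WT arrays split between the comparisons, which leaves fewer arrays to each, 1 gene was shared in each of 2 splits. In PAX5-G183S only the PAX5-activated genes were placed lower by camera, with 0 of 26 passing, 0 adjusted over the list alone (camera adjusted p = 0.0271, and adjusted p = 0.181 with an estimated correlation). In PAX5-G183V no list was called by camera.

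Within isolation batches PAX5-G183S gave 9 and 7 genes against PAX5-WT, with 4 shared, and fold changes in the batches had r = 0.101 across genes. PAX5-G183V gave 40 and 274 genes, with 2 shared and r = -0.0480, and with 3 transduction number series in place of the isolation batches 1009 genes differed, with 4 series 1. Without PAX5-WT replicate 6 the PAX5-G183V count was 5. PAX5-G183V and PAX5-G183S gave no gene that passed against each other among 17097 (limma, 0 genes; unadjusted p under 0.05 for 1526; smallest adjusted p = 0.0554), but 783 passed with 3 transduction number series in place of the isolation batches. With 4 series 0 passed, at a median SE of 0.156. Genes of MYC and ribosome biogenesis were higher in PAX5-G183V by camera (adjusted p = 0.000651, and adjusted p = 0.841 with an estimated correlation), with 0 of 18 passing over all genes and 3 higher and 1 lower adjusted over the list alone. Isolation batch 1 alone gave 23 genes and isolation batch 2 alone 111, with 0 shared, and without PAX5-G183S replicate 4 the pooled count was 14. In simulated data the comparison recovered 98% of 50 genes changed 1.5-fold and 50% of 50 genes changed 1.2-fold. The simulation held 200 changed genes, so these percentages may overstate what a comparison with 0 calls would find.

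PAX5-P80R was compared with MIR and with PAX5-WT to see what a change in the DNA-binding domain leaves, loses and adds. Some genes with large wild-type changes rose here as well: Nav3 rose by 4.99 ± 0.41 against MIR (SE, n = 6 and 7; limma adjusted p = 5.2e-11) and Ets1 by 2.87 ± 0.22. In isolation batches 1 and 2 Nav3 rose by 5.58 ± 0.29 and 4.26 ± 0.32 (4.59 ± 0.26 and 5.81 ± 0.30 in PAX5-WT), and Ets1 by 2.19 ± 0.25 and 3.63 ± 0.27 (adjusted p of the difference = 0.0407). Against MIR Cd36 at 0.64 ± 0.31 (adjusted p = 0.287), Ms4a1 at 0.17 ± 0.31 (0.871), Slamf6 at 0.0403 ± 0.40 and Siglecg at -0.22 ± 0.21 did not pass, where Cd36, Ms4a1 and Slamf6 were chosen after their values were seen. Without MIR replicate 7, however, Cd36 passed at 1.04 ± 0.27 (adjusted p = 0.02). Its values in the isolation batches were 0.14 ± 0.30 and 1.09 ± 0.32. Against PAX5-WT Cd36 fell by 5.67 ± 0.31, Ms4a1 fell by 5.12 ± 0.31, Fcgr2b fell by 3.47 ± 0.30, Siglecg fell by 2.65 ± 0.21 and Slamf6 fell by 2.63 ± 0.40. Asb9 and Mycn lay between the groups, at -2.01 ± 0.17 and -1.02 ± 0.15 against MIR, with Mycn at -1.33 ± 0.09 and -0.68 ± 0.10 in the batches (adjusted p of the difference = 0.0115). In Cd36, Ms4a1, Fcgr2b, Slamf6 and Siglecg all 6 PAX5-P80R arrays lay below every PAX5-WT array. Of the 613 genes that PAX5-WT raised 119 also rose with PAX5-P80R, and of the 486 it lowered 137 also fell, where unrelated lists would share 13.8 of the former. With the MIR arrays split, 95 and 116 genes were shared. Against PAX5-WT the change was smaller for 248 of the raised and 143 of the lowered genes.

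PAX5-P80R also moved genes beyond what PAX5-WT did. Ctsw, a cysteine protease gene, rose by 1.99 ± 0.14 against MIR and by 2.18 ± 0.14 against PAX5-WT (n = 6 and 7 in each; limma adjusted p = 5.0e-14 for the latter). Ackr3, a scavenging chemokine receptor gene, rose by 1.92 ± 0.10 and 1.88 ± 0.10. Neither gene passed in PAX5-WT against MIR, and all 6 PAX5-P80R arrays lay above every MIR and PAX5-WT array in both. The kinase gene Ipmk rose with PAX5-WT by 0.49 ± 0.13 and with PAX5-P80R by 1.64 ± 0.15, and the inhibitory receptor gene Klra17 fell by 0.84 ± 0.13 and by 1.61 ± 0.14. The interferon-induced genes Ifitm3 and Ifi44l rose by 2.52 ± 0.27 and 2.28 ± 0.23 against MIR, and with PAX5-WT by 0.91 and 1.21. Ifitm3 showed 144.5% of the PAX5-WT change in PAX5-G183S and 183.9% in PAX5-G183V, and Ifi44l 67.5% and 91.2%. Against MIR in isolation batches 1 and 2 Ctsw rose by 1.77 ± 0.17 and 2.19 ± 0.19 and Ackr3 by 1.73 ± 0.11 and 2.10 ± 0.12. The change was larger in isolation batch 2 for Klra17 (-0.97 ± 0.08 and -2.30 ± 0.09), Ifitm3 (1.75 ± 0.23 and 3.45 ± 0.25), Ifi44l (1.63 ± 0.23 and 3.13 ± 0.25) and Ipmk, with adjusted p of the difference at 9.8e-09, 0.0062, 0.0164 and 3.0e-06. In all 284 genes changed against MIR and, in the same direction, against PAX5-WT, 137 higher and 147 lower. Of these 284, 14 went in opposite directions in PAX5-WT and PAX5-P80R, among them Id3, at 0.59 ± 0.18 and -0.75 ± 0.21, and the cholesterol transport gene Npc1, at -0.35 ± 0.07 and 0.40 ± 0.08. Npc1, the PAX5-WT values of Ipmk, Klra17, Ifitm3 and Ifi44l, and the G183 values of the last 2, were chosen after their values were seen. Against MIR 385 genes rose and 422 fell, 807 together, and against PAX5-WT 457 were higher and 621 lower, 1078 together.

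**Figure D2:**
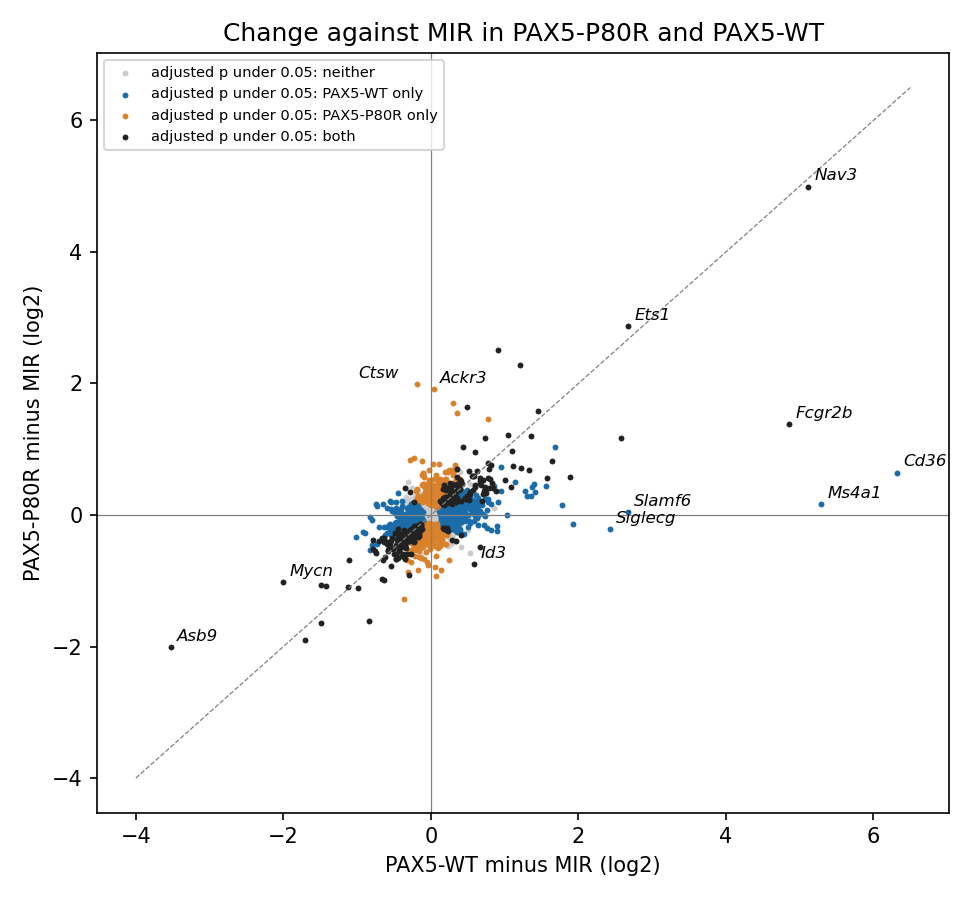
Change against MIR on the log2 scale in PAX5-WT (x axis) and PAX5-P80R (y axis), 1 point per gene, coloured by which comparison passed; the dashed line marks equal change. Nav3 and Ets1 lie on the line, Cd36, Ms4a1, Slamf6 and Siglecg far below it, and Ctsw and Ackr3 near a wild-type change of 0.

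Of 14 MHC class II genes 5 rose with PAX5-P80R against MIR (5 adjusted over the list alone; camera adjusted p = 0.00194, and adjusted p = 0.133 with an estimated correlation), but the rise differed between isolation batches. H2-Aa changed by 0.08 ± 0.15 in isolation batch 1 and by 2.88 ± 0.16 in isolation batch 2 (adjusted p = 1.1e-10 for the difference), H2-Ab1 by 0.09 ± 0.13 and 1.30 ± 0.15, Cd74 by 0.49 ± 0.12 and 1.45 ± 0.13, and H2-Eb1, chosen after its value was seen, by 0.17 ± 0.07 and 0.62 ± 0.08. Against PAX5-WT, H2-Aa was at -0.46 in isolation batch 1 alone (adjusted p = 0.0284). Trib2, a pseudokinase gene, changed by 0.35 ± 0.13 and 3.12 ± 0.15 against MIR. For H2-DMa, the other member that passed, the difference between the batches did not pass (adjusted p = 0.141). Of 23 B lineage transcription factors Ets1 rose by 2.87 ± 0.22, Ikzf1, chosen after its value was seen, by 0.26 ± 0.04 and Pax5 by 0.61 ± 0.17, while Id3 fell by 0.75 ± 0.21 (4 and 1 adjusted over the list alone; camera adjusted p = 0.00194, and adjusted p = 0.133 with an estimated correlation). The Pax5 change was -0.19 against PAX5-Δ2-6 arrays and did not pass (adjusted p = 0.704). Pax5 is the transduced gene, so its rise is no response to PAX5 if the probe set sees the construct. The list, which holds Pax5 in every comparison, was not tested without it.

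**Figure D3:**
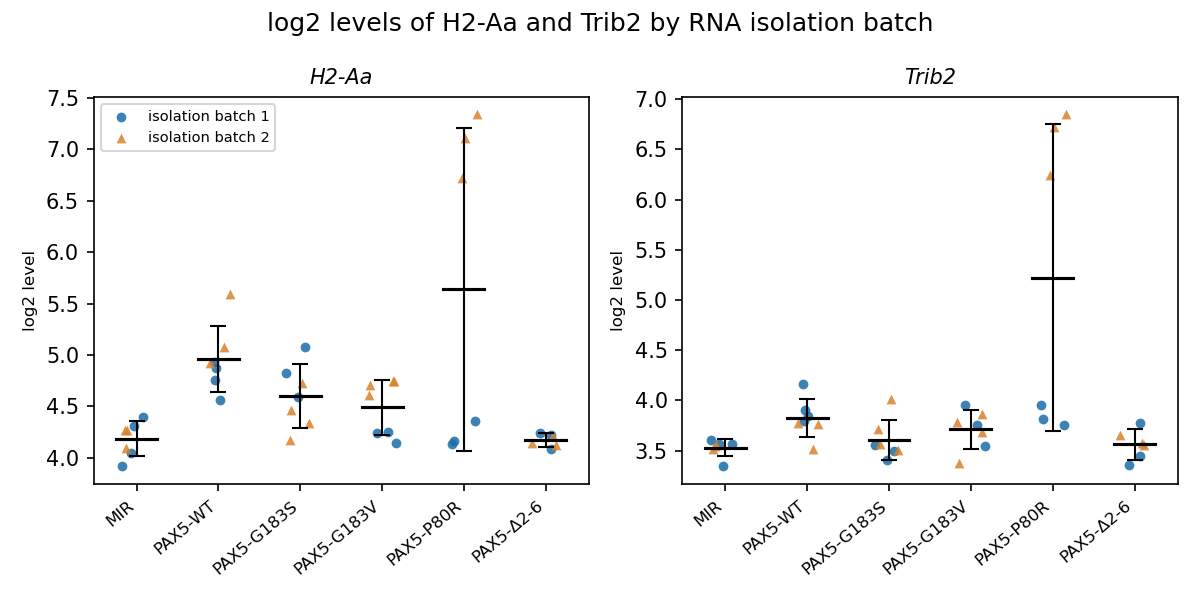
Levels of H2-Aa and Trib2 on the log2 scale (y axis) in every array of the 6 groups (x axis), with isolation batch 1 as circles, isolation batch 2 as triangles, and the mean with its SD in black. The PAX5-P80R arrays of isolation batch 2 stand above all other arrays in both genes.

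Of 25 interferon response genes 1 rose and 6 fell with PAX5-P80R against MIR, Irgm1 at 1.22 ± 0.08 and Mx1 at -0.83 ± 0.10 at the ends (1 and 7 adjusted over the list alone; camera adjusted p = 0.0355, and adjusted p = 0.133 with an estimated correlation). Of 18 genes of cholesterol synthesis 2 fell (4 adjusted over the list alone; camera adjusted p = 0.00194, and adjusted p = 0.133 with an estimated correlation), and of 18 genes of MYC and ribosome biogenesis 1 rose (5 adjusted over the list alone; camera adjusted p = 0.00194, and adjusted p = 0.556 with an estimated correlation). Against PAX5-WT 5 of 16 plasma cell identity genes were higher, with Ly6c1 at 0.67 ± 0.09, Derl3 at 0.40 ± 0.12, Fkbp11 at 0.24 ± 0.06 and Xbp1, chosen after its value was seen, at 0.20 ± 0.04 (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0014, and adjusted p = 0.353 with an estimated correlation). The fibroblast marker Col3a1 fell by 0.41 ± 0.11, and no other marker of the fibroblast, T cell, myeloid and erythroid lists passed there.

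The PAX5-P80R counts within isolation batches were 156 and 673 against MIR, with 85 shared in direction and 119 genes that changed by different amounts, and 488 and 737 against PAX5-WT, with 147 shared. With 3 transduction number series in place of the isolation batches they were 1714 and 1643, with 4 series 70 and 37. Under 4 series 781 of the 807 and 1030 of the 1078 genes kept their sign, with a median SE of 0.185 (0.0755 for PAX5-WT against MIR). Against PAX5-Δ2-6 arrays of the same series and plate PAX5-P80R differed at 565 genes, 333 higher and 232 lower.

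PAX5-Δ2-6 was compared with MIR to see whether this construct moved any gene. Nav3, Cd36, Ms4a1 and Fcgr2b lay at -0.08 ± 0.41, -0.39 ± 0.31, -0.028 ± 0.31 and -0.078 ± 0.30 against MIR, and Mycn at 0.13 ± 0.15. None of 17097 genes passed (limma, 0 genes; n = 6 and 7; unadjusted p under 0.05 for 1308, 643 higher and 665 lower; smallest adjusted p = 0.218). With 3 transduction number series in place of the isolation batches 677 genes passed, 269 higher and 408 lower, so the count of 0 depends on how batches are modelled. That fit rests on isolation batch 2 for this comparison. There PAX5-Δ2-6 and MIR come from different transduction series, so these calls cannot be told from a difference between series. In simulated data this comparison recovered 94% of 50 genes changed 1.5-fold and 40% of 50 genes changed 1.2-fold, so smaller changes would often be missed. The simulation held 200 changed genes, up to 4-fold, and no difference between series. With fewer changed genes the adjusted threshold is stricter, so these percentages may overstate what a comparison with 0 calls would find. With no member passing, camera placed 3 lists apart from other genes: the interferon response lower (adjusted p = 0.00664, and adjusted p = 0.0676 with an estimated correlation; 1 of 25 lower adjusted over the list alone), MYC and ribosome biogenesis higher (adjusted p = 0.00664, and adjusted p = 0.794 with an estimated correlation; 0 of 18 adjusted over the list alone) and cholesterol synthesis lower (adjusted p = 0.0301, and adjusted p = 0.749 with an estimated correlation; 0 of 18 adjusted over the list alone). The Pax5 probe set was 0.80 ± 0.17 above MIR without passing (adjusted p = 0.22). This was the largest change in size of any gene here, and all 6 PAX5-Δ2-6 arrays lay above every MIR array. Isolation batch 1 alone gave 4 genes and isolation batch 2 alone 56, with 0 shared, and 36 genes changed by different amounts in the 2 batches.

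Against PAX5-WT, PAX5-Δ2-6 differed at 1195 genes, 481 higher and 714 lower. They held 420 of the 613 genes that PAX5-WT raised and 290 of the 486 it lowered, each with a smaller change in PAX5-Δ2-6. The other genes were not called in PAX5-WT against MIR, and both comparisons use the PAX5-WT arrays. Cd36 fell by 6.70 ± 0.31 (SE, n = 6 and 7; limma adjusted p = 1.7e-18), Ms4a1 fell by 5.32 ± 0.31, Nav3 fell by 5.19 ± 0.41 and Ets1 fell by 2.96 ± 0.22, while Asb9 was 3.52 ± 0.17 and Mycn 2.14 ± 0.15 higher. Of 16 plasma cell identity genes 4 were higher, Ly6c1 by 1.00 ± 0.09 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00358, and adjusted p = 0.19 with an estimated correlation). Of 14 MHC class II genes 5 were lower, H2-DMa at -1.36 ± 0.18 (5 adjusted over the list alone; camera adjusted p = 0.00358, and adjusted p = 0.19 with an estimated correlation). Of 27 cell cycle genes 3 were higher (6 adjusted over the list alone; camera adjusted p = 0.00445, and adjusted p = 0.19 with an estimated correlation), and of 23 B lineage transcription factors 4 were lower (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0172, and adjusted p = 0.19 with an estimated correlation). Among other cell types the fibroblast marker Vim fell by 0.95 ± 0.24 and the myeloid marker Cebpb rose by 0.19 ± 0.06, though with 4 transduction series in place of the isolation batches Cebpb was at -0.0374 (adjusted p = 0.995). Isolation batch 1 alone gave 588 genes and isolation batch 2 alone 706, with 226 shared, and in place of the isolation batches 3 transduction number series gave 1596 and 4 series 58.

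The share of the wild-type response was scored in each array with genes chosen in the other isolation batch from the PAX5-WT and MIR arrays alone, 443 genes chosen in batch 1 and 157 in batch 2, so that MIR lies at 0% and PAX5-WT at 100%. PAX5-G183S scored 92.0% ± 7.35 (SD, n = 7), above MIR by an exact two-sided permutation within isolation batches (p = 0.000816, the smallest that 1225 relabellings allow; BH-adjusted p = 0.00229) and below PAX5-WT before adjustment (exact permutation p = 0.0416; BH-adjusted p = 0.0555 over 8 tests). Scored on the genes PAX5-WT raised or on those it lowered, PAX5-G183S lay at 92.3% and 92.6% and its difference from PAX5-WT did not pass. PAX5-G183V scored 96.8% ± 12.1 (SD, n = 7), with 84.0% in isolation batch 1 and 106% in isolation batch 2, and its mean over both did not differ from PAX5-WT (exact permutation p = 0.471; BH-adjusted p = 0.471). That mean averages opposite shifts. In isolation batch 1 its arrays reached at most 85.3% and PAX5-WT arrays at least 91.5%. In isolation batch 2 its arrays lay at 103.9% to 108.3% and PAX5-WT arrays at 97.3% to 104.5%. On genes changed at least 2-fold it scored 91.5% (exact permutation p = 0.00571 against PAX5-WT). PAX5-P80R scored 48.8% ± 9.33 (SD, n = 6), with 40.6% and 57.0% in the isolation batches, and differed from MIR and from PAX5-WT (exact permutation p = 0.00143 each, the smallest that 700 relabellings allow; BH-adjusted p = 0.00229). Its score was 41.9% over genes PAX5-WT raised and 64.7% over genes it lowered, a difference that was not tested. PAX5-Δ2-6 scored -2.80% ± 3.62 (SD, n = 6), which did not differ from MIR (exact permutation p = 0.206; BH-adjusted p = 0.235).

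**Figure D4:**
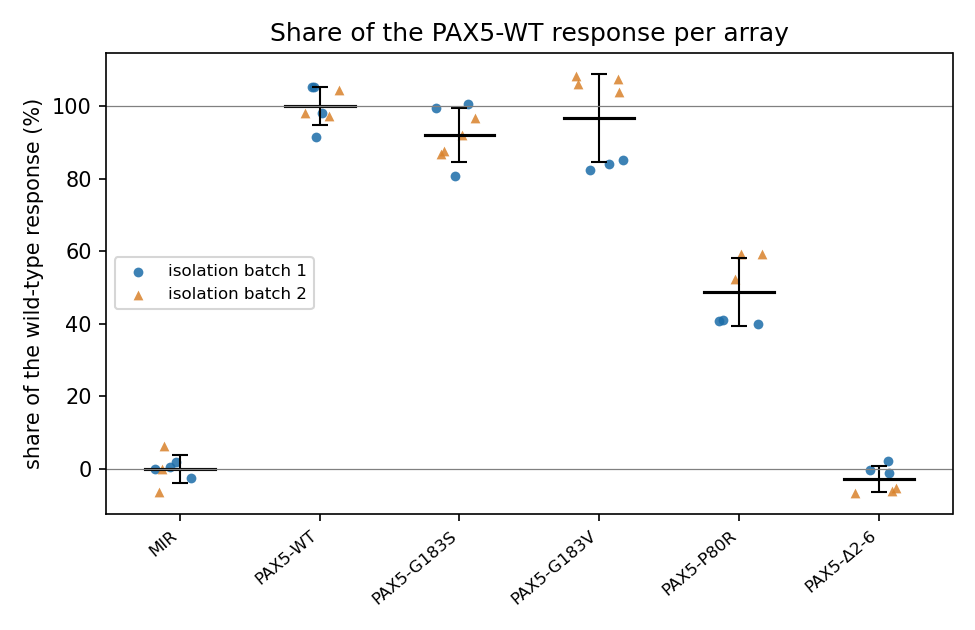
Share of the PAX5-WT response in percent (y axis) for every array of the 6 groups (x axis), with isolation batch 1 as circles, isolation batch 2 as triangles, and the mean with its SD in black; grey lines mark 0% and 100%. PAX5-P80R arrays lie between 39.9% and 59.3%, below all PAX5-G183S and PAX5-G183V arrays and above all PAX5-Δ2-6 arrays.

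Across 17097 genes, which are not independent replicates, the changes against MIR correlated with those of PAX5-WT at r = 0.867 for PAX5-G183S, 0.819 for PAX5-G183V, 0.473 for PAX5-P80R and 0.135 for PAX5-Δ2-6. The MIR arrays are shared by both sides of each correlation, and unchanged groups simulated against shared controls gave a mean r of 0.491, 0.467, 0.420 and 0.453 and a highest r of 0.853, 0.778, 0.737 and 0.819. The PAX5-P80R and PAX5-Δ2-6 values thus lay inside the simulated range. With the MIR arrays split between both sides the values were 0.722, 0.684, 0.351 and 0.00241.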

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

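Of the tests in this part, those of the transduction series and of the plate for the genes PAX5-P80R moved beyond PAX5-WT, that of these genes in each isolation batch that of the 5 genes lower in both G183 groups, with its limit of 3 SE, and that of genes chosen in one isolation batch and measured in the other were chosen after the result was seen.

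In 23 of 552 groups of arrays 1 array lay far from the others of its group, and chance gives about 1 in 20. MIR replicate 7 stood highest in Cd36 at 5.89 (other MIR arrays 3.56 to 3.85, PAX5-WT mean 10.35), in P2ry10 at 3.51 and in Derl3 at 6.13. It also lay above every other MIR array in Fcgr2b at 5.58 (others 4.12 to 4.92) and Nav3 at 4.53 (3.84 to 4.34), though not in Ms4a1 at 4.07 (up to 4.08). MIR replicate 1 was lowest in Trib2 at 3.35 and in Inpp4b at 4.08, and MIR replicate 6 in Spi1 at 6.21. Among PAX5-WT arrays, replicate 7 was highest in Eaf2 at 10.95, and replicate 4 lowest in Tspan15 at 7.49 and in Spi1 at 6.49. Among PAX5-G183S arrays, replicate 2 was highest in Siglecg at 7.53, replicate 7 highest in Cd79a at 4.60 and replicate 4 lowest in Igtp at 8.37. Among PAX5-G183V arrays, replicate 5 was lowest in Ifi44l at 5.33, replicate 2 in Lpxn at 5.68, replicate 7 in Lair1 at 5.89 and replicate 3 in Cebpb at 10.62. Among PAX5-P80R arrays, replicate 1 was highest in Pdia4 at 11.09 and replicate 4 in Ell2 at 11.51, and replicate 3 was lowest in Epsti1 at 5.43 and in Notch1 at 7.00. Among PAX5-Δ2-6 arrays, replicate 4 was highest in Il13ra1 at 7.59, replicate 3 highest in Klhl14 at 3.54 and replicate 1 lowest in Ly6c1 at 8.65.

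Probe sets that name no single gene, which enter no comparison above, changed as well. Of 16243 such probe sets limma called 325 for PAX5-WT against MIR, 314 for PAX5-G183S, 500 for PAX5-G183V, 207 for PAX5-P80R and 0 for PAX5-Δ2-6. The probe set with the largest rise was the same in PAX5-WT, PAX5-G183S, PAX5-G183V and PAX5-P80R, at 3.53, 3.19, 2.67 and 1.96.

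Other splits of the same arrays into groups of the same sizes, 100 for each comparison, show how often mixed groups give as many genes. These splits took no account of isolation batch or transduction series. Only 1 of 100 splits, the real one, gave as many for PAX5-WT against MIR (1099 genes, highest other split 389), PAX5-G183S against MIR (1046, 480) and PAX5-G183S against PAX5-WT (13, 6). The same held for PAX5-G183V against MIR (1586, 620), PAX5-P80R against MIR (807, 420), PAX5-G183V against PAX5-WT (25, 1), PAX5-P80R against PAX5-WT (1078, 30) and PAX5-Δ2-6 against PAX5-WT (1195, 169). There the real split also parts the transduction series, so the splits cannot tell group from series. For PAX5-Δ2-6 against MIR (0, 1) and PAX5-G183V against PAX5-G183S (0, 228) limma called 0 genes (unadjusted p under 0.05 for 1308 and 1526), so all 100 splits necessarily gave as many and decide nothing. In the latter a split called many more genes than the real one, which points to a structure of the samples other than the groups.

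Genes called within isolation batch 2 alone (56 for PAX5-Δ2-6 against MIR and 111 for PAX5-G183V against PAX5-G183S) were not shared with isolation batch 1. These comparisons share no array but, for all but 1 array, part the same transduction series, and their changes correlated across genes in isolation batch 2 at r = 0.457 (highest of 100 shuffled draws 0.522, SD 0.183), which is consistent with a difference between transduction series, while in isolation batch 1 r was -0.0360 (SD of draws 0.191) and decided nothing. Without 3 arrays that stand apart (PAX5-G183S replicate 7, PAX5-G183V replicate 5 and PAX5-P80R replicate 4) the PAX5-G183V count in isolation batch 2 was 1 in place of 111. The PAX5-Δ2-6 count was 19 in place of 56. Both G183 groups then hold fewer arrays, so whether these 3 arrays carry the PAX5-G183V calls stays open. An effect of PAX5-Δ2-6 present in both batches stays open, as its changes in the batches correlated at r = 0.00323 (highest draw 0.146, SD 0.0571). Genes are not independent replicates, and only 1 array, PAX5-G183S replicate 4 of transduction 45, parts series from construct. Its Nav3 and Ms4a1 levels were 7.39 and 9.16. Other PAX5-G183S arrays of isolation batch 2 lay at 9.46 to 9.59 and 7.85 to 8.15, and PAX5-G183V arrays there at 7.44 to 7.77 and 9.25 to 9.46. In both genes this array lay with its series, while its Mycn level of 11.69 lay between the groups. With 1 array, series and construct cannot be told apart across genes.

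PAX5-P80R moved 284 genes beyond PAX5-WT. The tables argue against a transduction series effect common to all constructs as the whole cause. PAX5-Δ2-6 arrays of the same series showed a median of 23.2% of the change (quartiles 5.88% and 41.4%), and 157 of these genes were called against PAX5-Δ2-6 in the same direction. A series effect that needs an active PAX5 construct stays open, since PAX5-Δ2-6, where no gene passed against MIR, could not show it. Plate 2 arrays alone kept a median of 99.7% of the change against PAX5-WT (quartiles 91.8% and 107%). This decides little about the plate. The fit already had a plate term, and the genes were chosen with the same PAX5-P80R arrays, so a share near the full change was likely beforehand. The tables also argue against a weaker response of the wild-type kind as the whole cause, since 18 genes were called beyond PAX5-WT in the same direction in each isolation batch on its own, where unrelated lists would share 0.425. For the other genes, apart from 13 called in opposite directions in PAX5-WT and PAX5-P80R, which it would not give, such a response stays open: over 384 genes chosen in one isolation batch the median signed difference in the other was 0.13, with 72.4% keeping their sign, under the 75% set beforehand.

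Klhl14, Themis2, Lca5, Fam111a and 4833439L19Rik were lower than PAX5-WT in both G183 groups. PAX5-WT lay above MIR by 0.76 in Klhl14, 0.84 in Lca5 and 0.91 in Fam111a, but only by 0.17 in Themis2, and at -0.0011 in 4833439L19Rik. In Themis2 and 4833439L19Rik all 7 arrays of each G183 group lay below every MIR array. For 40 genes chosen with one part of the PAX5-WT arrays, the median PAX5-G183S difference against the other arrays was -0.0832 (quartiles -0.51 and 0.01), so the shared arrays cannot be ruled out for the wider set. The tables argue against a response smaller by one factor at every gene: for Klhl14, Lca5, Themis2, Fam111a, Rbms1 and Slamf6, called lower in both groups in one isolation batch, the median excess beyond it in the other was -0.50 (quartiles -0.68 and -0.38), though Slamf6 in PAX5-G183V lay at 0.34. For the wider set it stays open (median excess -0.10, quartiles -0.43 and 0.01), as for 4833439L19Rik. The choice of the 5 genes as called alone puts each over 3 SE below the prediction, at -3.71 SE or lower, where the nearest observed value was -4.50. An altered octapeptide remains an untested biological explanation.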

How the results depend on the processing

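The settings chosen after seeing the data were leaving out 3 arrays, 4 transduction series and PAX5-Δ2-6 as the control. Over 401 pairs of a named gene and a comparison, 5991 of 6669 values under alternatives kept their direction and side of the threshold, 559 no longer passed, 112 passed anew and 7 reversed. With 1 array left out, 5232 of 5448 did, 179 no longer passed, 37 passed anew and 0 reversed. The scaling alternatives moved the median change by at most 0.01. Signals near background limit what the arrays show of Pax5 and Cd79a, and the size of changes from low MIR levels, as in Cd36, Ms4a1 and Nav3. Except where fewer arrays or genes or a stricter threshold explain a change, the cause was not tested.

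With isolation batch 1 arrays alone the counts were 646 (PAX5-G183S against MIR), 302 (PAX5-G183V), 156 (PAX5-P80R) and 4 (PAX5-Δ2-6), and 40 (PAX5-G183V against PAX5-WT), 488 (PAX5-P80R), 588 (PAX5-Δ2-6) and 23 (PAX5-G183V against PAX5-G183S). H2-Aa and Trib2 in PAX5-P80R against PAX5-WT turned to -0.46 and -0.0817, and the PAX5-G183S share was 93.7%. With isolation batch 2 arrays alone they were 229 (PAX5-WT against MIR), 319 (PAX5-G183S) and 56 (PAX5-Δ2-6), and 7 (PAX5-G183S against PAX5-WT), 274 (PAX5-G183V), 706 (PAX5-Δ2-6) and 111 (PAX5-G183V against PAX5-G183S). Pmaip1 in PAX5-G183S against MIR turned to 0.000259, and shares were 90.8% (PAX5-G183S), 57.0% (PAX5-P80R) and -5.93% (PAX5-Δ2-6).

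With plate 1 arrays alone the counts were 427 (PAX5-WT against MIR), 553 (PAX5-G183S), 693 (PAX5-G183V), 2 (PAX5-G183S against PAX5-WT) and 1 (PAX5-G183V). With plate 2 arrays alone they were 225 (PAX5-WT against MIR), 153 (PAX5-G183S), 211 (PAX5-G183V), 198 (PAX5-P80R), 5 (PAX5-G183S against PAX5-WT), 1 (PAX5-G183V), 478 (PAX5-P80R) and 589 (PAX5-Δ2-6), the shares 86.8% (PAX5-G183S) and 98.1% (PAX5-G183V), and Cd6 in PAX5-G183S against MIR turned to -0.000685. No batch terms gave 696 (PAX5-WT against MIR), 4 (PAX5-G183V against PAX5-WT), 697 (PAX5-P80R) and 1 (PAX5-G183V against PAX5-G183S), and a random block for plate by isolation batch gave 1 for the last. Fitting only the 2 groups compared gave 148 (PAX5-P80R against MIR), 1 (PAX5-Δ2-6), 7 (PAX5-G183S against PAX5-WT), 275 (PAX5-P80R) and 576 (PAX5-Δ2-6).

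With 3 transduction number series in place of the isolation batch the counts rose to 2420 (PAX5-G183V against MIR), 1714 (PAX5-P80R), 677 (PAX5-Δ2-6), 1009 (PAX5-G183V against PAX5-WT), 1643 (PAX5-P80R) and 783 (PAX5-G183V against PAX5-G183S). With 4 series they were 123 (PAX5-G183V against MIR), 70 (PAX5-P80R), 1 (PAX5-G183V against PAX5-WT), 37 (PAX5-P80R) and 58 (PAX5-Δ2-6), where 1 array links the series, and Notch1 in PAX5-P80R and Cebpb in PAX5-Δ2-6 against PAX5-WT turned to -0.0446 and -0.0374. With PAX5-Δ2-6 as the control PAX5-G183V gave 852, and Pax5 in PAX5-P80R turned to -0.19. Without the 3 arrays that stand apart PAX5-G183V against PAX5-WT gave 12.

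A block for the replicate number beside plate and isolation batch gave 173 (PAX5-P80R against MIR), 16 (PAX5-G183V against PAX5-WT), 202 (PAX5-P80R) and 379 (PAX5-Δ2-6). Of 96 same-number pairs 10 had a residual correlation over 0.1, and 4 of 40 arrays matched their own number best, so the numbers were not taken as pairs.

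A 1.5-fold minimum left 145 (PAX5-WT against MIR), 134 (PAX5-G183S), 153 (PAX5-G183V), 96 (PAX5-P80R), 5 (PAX5-G183S against PAX5-WT), 3 (PAX5-G183V), 118 (PAX5-P80R) and 174 (PAX5-Δ2-6). Trend and robust settings gave 43 for PAX5-G183V against PAX5-WT and 6 for PAX5-G183V against PAX5-G183S, genes above the median level alone 52 and 1, arrays centred on their medians 1 for the latter and the mean of all probe sets 3. With an estimated correlation camera called 0 lists in the 9 comparisons where the preset called any. Fry called 1 (PAX5-Δ2-6 against MIR), 0 (PAX5-G183S against PAX5-WT), 7 (PAX5-P80R against PAX5-WT) and 0 (PAX5-G183V against PAX5-G183S).

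The PAX5-G183S share was 92.3% over genes PAX5-WT raised and 92.6% over genes it lowered, without passing against PAX5-WT, the PAX5-G183V share 91.5% over genes changed at least 2-fold, which passed, and the PAX5-Δ2-6 share 4.78% with genes chosen and scored on all arrays. Splitting the MIR arrays in 2 parts gave correlations with PAX5-WT of 0.722, 0.684, 0.351 and 0.00241 for PAX5-G183S, PAX5-G183V, PAX5-P80R and PAX5-Δ2-6, and genes above the median level 0.923 and 0.873 for PAX5-G183S and PAX5-G183V.

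With 1 array left out PAX5-Δ2-6 against MIR ranged from 0 to 1 (without PAX5-Δ2-6 replicate 3), PAX5-G183V against PAX5-G183S from 0 to 14 (without PAX5-G183S replicate 4), PAX5-G183V against PAX5-WT from 5 (without PAX5-WT replicate 6) to 33, and the PAX5-G183S share from 90.2% to 94.0%.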
